A study of Homo sapiens with 27 samples.

How the data were processed

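RNA of 27 samples of MDA-MB-231 cells was hybridised to Affymetrix Clariom S human arrays. The 9 groups of 3 samples were taken from the sample titles: a control miRNA, mock, and 7 miRNAs, each transfected at 50 nM and harvested after 48 h per the labels. What the mock samples received is not described in the labels. Per the series' design text the raw data were processed by a core facility. The deposited values are normalized probe set intensities on a linear scale, made by the authors from the raw arrays. The tool, the background correction and the version were not given in the sources used here, and quantile normalization is known only from the name of a deposited table. That normalization gives arrays nearly the same distribution, so a change in the total amount of messenger RNA would not be seen and differences are relative to the other genes. The 2 deposited tables hold the same intensity values (largest relative difference 5e-10). The table whose columns name single samples supplied the values, and the other table supplied the annotation.

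Of 27189 probe sets, 20893 belong to the main category. Of these, 17683 had 1 gene symbol and entered, 2007 had several and were left out, and 1203 had none in the annotation used here and are not reported here. A symbol was looked up in a RefSeq gene table of GRCh38.p14, which held 16823 of the symbols, and 952 were updated. The deposited annotation names no build, but the positions of 99.4% of 16575 genes overlap those of GRCh38.p14. Removing 4 probe sets with a missing value and keeping the probe set with the highest mean where a gene had several (931 genes) left 16636 genes. The values were taken to log2 without a pseudocount or an intensity filter. The median of 23 antigenomic background probe sets averaged 5.94 in log2, and 88.0% of the genes had a mean above it. Each intensity column used was assigned to a sample or group, and further per-sample columns of the annotated table were not used. The number of arrays limits the precision, and so does their quality, since replicate 1 of miR-4672 had a raised background (antigenomic median 68.5).

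Each miRNA and mock was compared with the control miRNA with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, defaults). All 27 arrays entered 1 fit with 9 group means, leaving 18 residual degrees of freedom and 4.11 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called changed at an adjusted p under 0.05. Differences among the 9 groups were tested with the limma F test. NT5E was also adjusted over the 8 comparisons and tested by an exact two-sided permutation of 3 against 3 arrays (20 assignments). Fixed lists of 24 pathways and processes and 5 sets of cell type markers were tested with camera at a preset inter-gene correlation of 0.01, two-sided, and adjusted over all 232 tests. A list was called at an adjusted p under 0.05, members were counted at adjusted p under 0.05 over all genes and, separately, adjusted over the list alone, and camera was repeated with an estimated correlation. Of 69 calls, 37 held with it. Random regroupings of the arrays gave up to 58 calls at the preset correlation, so a call at that setting alone is weak evidence. Statements that genes or lists changed refer to limma and camera adjusted p-values. Python 3.11.15 with pandas 2.3.3 prepared the tables and drew the figures (matplotlib 3.10.9).

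The genes named in the results were set by a rule fixed before the data were examined, as were the lists, the tests of the comparisons and all but 2 of the alternatives. Some genes and tests of the closing section were chosen later, as stated there. The rule took NT5E and, for each miRNA, the 10 highest and 10 lowest log2 fold changes among genes at adjusted p under 0.05 that did not overlap between the 3 miRNA and 3 control arrays and had a mean above the median of all genes (7.50 in log2) in the higher group. For mock it took 5 each way, for genes shared by all 7 miRNAs the 5 highest and 5 lowest by their smallest absolute change, and for each called list up to 4 members with the largest absolute change at adjusted p under 0.05. Genes with placeholder names were passed over.

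The pipeline was tested on simulated data with the spread of the real arrays. In the miR-134-3p comparison over 16636 genes, 8% of genes changed by 0.25 in log2 were recovered, 44% at 0.5, 96% at 1 and 100% at 2, and 5 unchanged genes were called. Far fewer genes were changed in the simulation than were called under the real miRNAs. The adjusted threshold was therefore stricter there, and recovery in the real data may be higher. Counts of shared genes and correlations were compared with 100 simulated sets of unchanged groups against the same controls. Alternatives changed the scaling, filter, variance model, array weights, arrays in the fit, baseline, thresholds, probe sets per gene, list test and replicates, 1 at a time except that the variance model took a trend with intensity and robust estimation together. Replicate numbers in the labels did not pair the samples by the check described in the closing section, so no block was used. Whether transcripts with a seed match to a miRNA moved was not analysed here, since no 3' untranslated region annotation was at hand.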

Results

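Gene expression was measured in MDA-MB-231 cells, an established human triple-negative breast cancer line of mesenchymal character, 48 h after transfection with a 50 nM dose of a microRNA (miRNA). The 27 Affymetrix Clariom S arrays fell into 9 groups of 3. These were a non-targeting control miRNA with a plant sequence, a mock group, and the miRNAs miR-134-3p, miR-224-3p, miR-34b-3p, miR-4672, miR-3126-5p, miR-6859-3p and miR-6514-5p. The study selected these 7 miRNAs as ones that raise NT5E, the gene of the ecto-nucleotidase CD73, which converts extracellular AMP to adenosine. Each miRNA was therefore set against the control miRNA to ask what it did to NT5E and to the other transcripts. The values were normalized probe set intensities with nearly equal distributions, the array medians lying between 171 and 187. Arrays of the same group correlated at 0.9735 to 0.9910 across probe sets, and no pair held identical values. In all, 16636 genes were tested, and the mean of 88.0% of them lay above the antigenomic background. The number of arrays limited the precision, and the median standard deviation of a gene within a group was 0.16 on the log2 scale. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

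NT5E was strongly expressed in every group and rose under miR-6859-3p, miR-3126-5p and miR-6514-5p. Its probe set (TC0600008697.hg.1, 10 probes, chromosome 6, 85449584 to 85495791, plus strand in the deposited annotation) read 5396 ± 117 (SD, n = 3) with the control miRNA and 5624 ± 213 in mock. It read 6948 ± 145 under miR-6859-3p, which was 1.29-fold the control (log2 fold change 0.36 ± 0.06, SE, limma adjusted p = 3.3e-04 over all genes). The change was 1.21-fold under miR-3126-5p (6543 ± 229, adjusted p = 0.0023) and 1.18-fold under miR-6514-5p (6378 ± 191, adjusted p = 0.0068). The means under the other 4 miRNAs were 5951 ± 108 for miR-134-3p, 5990 ± 124 for miR-224-3p, 5919 ± 265 for miR-34b-3p and 6061 ± 226 for miR-4672. These were 1.10-fold to 1.12-fold the control, with adjusted p from 0.083 to 0.24 over all genes. When the 8 comparisons of NT5E alone were adjusted together, all 7 miRNAs passed, with adjusted p of 3.9e-05 for miR-6859-3p and up to 0.046 for miR-34b-3p, while mock did not (0.34). For each miRNA all 3 arrays lay above all 3 control arrays, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 allows. Between the miRNAs, NT5E was higher under miR-6859-3p than under miR-134-3p, miR-224-3p, miR-34b-3p and miR-4672 (log2 differences of these 4 minus miR-6859-3p from -0.23 to -0.20, limma adjusted p from 0.014 to 0.019 over 21 pairs). It did not differ by this test from its level under miR-3126-5p (adjusted p = 0.27) or miR-6514-5p (adjusted p = 0.14). NT5E was a small part of each response: under miR-6859-3p it ranked 941 among all genes ordered by log2 fold change. With a variance model that is robust and allows a trend with intensity, both at once, the other 4 miRNAs also passed over all genes (adjusted p from 0.0065 to 0.043), and with only the 6 arrays of the comparison the miR-6514-5p change did not (adjusted p = 0.086). Against mock the log2 fold changes of miR-6859-3p (0.31), miR-3126-5p (0.22) and miR-6514-5p (0.18) passed over all genes (adjusted p = 0.0024, 0.021 and 0.047). Those of miR-134-3p (0.08), miR-224-3p (0.09), miR-34b-3p (0.07) and miR-4672 (0.11) did not (adjusted p from 0.29 to 0.67).

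**Figure D1:**
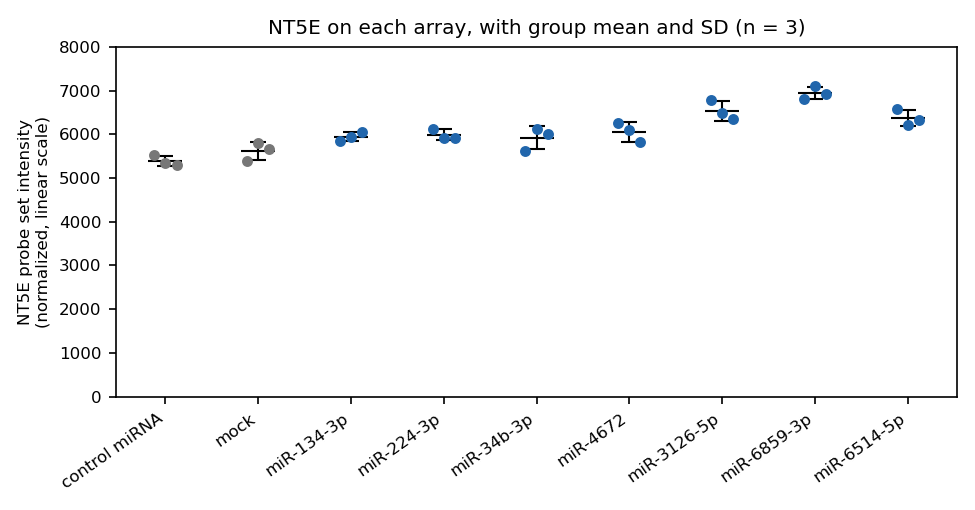
Normalized linear intensity of the NT5E probe set (vertical axis) on each of the 27 arrays, by group (horizontal axis), with the group mean and SD (n = 3). The points of miR-6859-3p lie between 6820 and 7105 and those of the control miRNA between 5308 and 5529.

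The transcriptome changed widely under every miRNA and little in mock. At a limma adjusted p under 0.05, 2822 genes changed under miR-6514-5p, 2624 under miR-134-3p, 2455 under miR-3126-5p, 2357 under miR-224-3p, 1928 under miR-4672, 1416 under miR-6859-3p and 1283 under miR-34b-3p, against 133 in mock. Rises made up 47.3% to 52.4% of the changes under 6 of the miRNAs, 58.3% under miR-6859-3p and 81.2% in mock. Under each miRNA the changes of at least 2-fold were mostly falls (70.1% to 90.9%). Under miR-6514-5p 239 genes fell and 24 rose by that much, under miR-134-3p 141 fell and 34 rose, and under miR-34b-3p 29 fell and 9 rose. Over all 9 groups together, 6785 genes (40.8%) differed by the limma F test, NT5E among them (adjusted p = 8.9e-04). With only the 6 arrays of a comparison in the fit, the counts fell to 739 for miR-34b-3p (334 higher), 682 for miR-4672 (324 higher), 885 for miR-6859-3p (472 higher) and 0 for mock, where 1505 genes were at an unadjusted p under 0.05 in the fit of all arrays. The balance of rises and falls moved by over 10 points when arrays were centred on housekeeping genes, to 1951 higher and 1020 lower for miR-134-3p, 1873 and 860 for miR-224-3p, 919 and 520 for miR-34b-3p, 618 and 727 for miR-6859-3p, and 1119 and 1551 for miR-6514-5p. With mock as the baseline it moved as far towards falls for miR-34b-3p, with 316 higher and 512 lower, and for miR-3126-5p, with 698 and 1047, and miR-6859-3p had 535 higher. Without control replicate 1 the number of higher genes was 442 for miR-34b-3p, from 667, and 542 for miR-6859-3p, from 825.

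**Figure D2:**
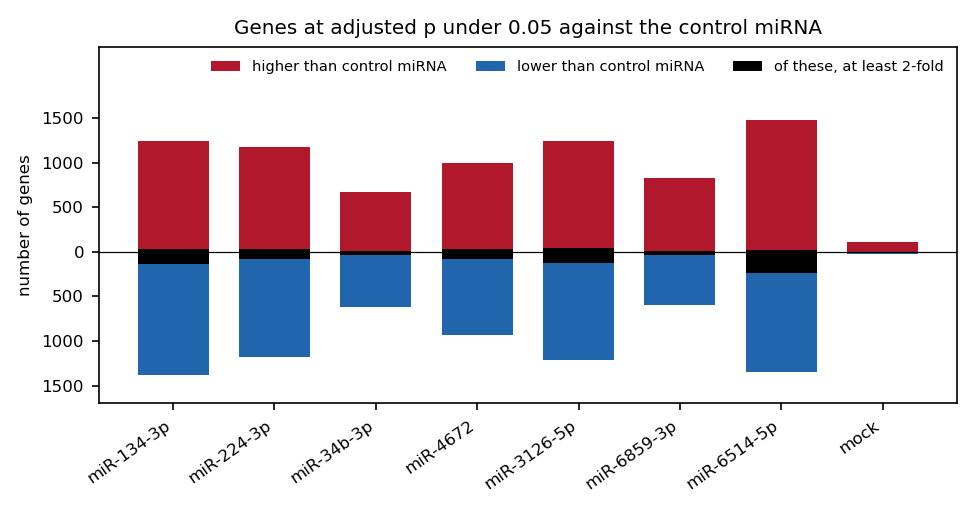
Number of genes (vertical axis) at limma adjusted p under 0.05 in each comparison against the control miRNA (horizontal axis), higher above the zero line and lower below it, with the part changed at least 2-fold in black. The bars reach 1479 higher and 1343 lower genes for miR-6514-5p and 108 and 25 for mock.

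The list of DNA replication and S phase genes was lower under all 7 miRNAs, though few of its members passed the test under miR-6859-3p. With 36 measured members, it had its lowest median under miR-6514-5p (log2 fold change -1.27), followed by -1.04 under miR-134-3p, -1.02 under miR-3126-5p, -0.82 under miR-224-3p, -0.68 under miR-34b-3p, -0.34 under miR-4672 and -0.22 under miR-6859-3p. Under miR-6514-5p all 36 members fell, under miR-134-3p, miR-224-3p and miR-3126-5p 33 each, under miR-34b-3p 29, under miR-4672 15 and under miR-6859-3p 7. Adjusted over the list alone, these counts were 36, 35, 36, 33, 31, 24 and 12 in the same order of miRNAs. Examples are DTL, which targets the licensing factor CDT1 for destruction and fell by 2.22 under miR-6514-5p and by 1.92 under miR-134-3p, and PCNA, the sliding clamp of DNA polymerase, which fell by 1.63 under miR-134-3p. RRM1, a subunit of ribonucleotide reductase, fell by 1.99 under miR-6514-5p. The camera test called the list lower under every miRNA (adjusted p from 2.7e-49 to 1.8e-07), and these 7 calls held with an estimated correlation between genes (adjusted p from 3.3e-05 to 0.046).

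The mitosis and G2/M phase list (36 measured) had medians of -1.03 under miR-6514-5p, -0.84 under miR-3126-5p, -0.63 under miR-134-3p, -0.62 under miR-224-3p, -0.57 under miR-34b-3p, -0.35 under miR-6859-3p and -0.14 under miR-4672. All 36 members fell under miR-6514-5p, 31 under miR-3126-5p, 28 under miR-134-3p, 27 under miR-224-3p, 24 under miR-34b-3p and 14 under miR-6859-3p. Adjusted over the list alone, these counts were 36, 31, 30, 31, 32 and 21. These 6 calls held with an estimated correlation (adjusted p from 3.3e-05 to 0.0043). PLK1, a mitotic kinase, fell by 1.98 and FOXM1, a transcription factor of G2/M genes, by 2.07 under miR-3126-5p. Under miR-4672 only 3 members fell, among them PLK1 (by 1.23) and AURKB (by 0.98), and 2 rose (4 and 3 adjusted over the list alone). That call ended with an estimated correlation (adjusted p = 0.29), without replicate 1 of miR-4672 (median -0.06, adjusted p = 0.18), without the dimmest genes (adjusted p = 0.055), and against mock (median 0.02, adjusted p = 0.88). Against mock the median under miR-6859-3p was -0.21, and AURKB under miR-4672 fell by 0.62.

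Transcripts of the replication-dependent histones, made in S phase, were lower as well. The median of 48 measured histone genes was -1.04 under miR-6514-5p, -0.75 under miR-3126-5p, -0.59 under miR-134-3p, -0.58 under miR-34b-3p, -0.46 under miR-224-3p, -0.45 under miR-6859-3p and -0.38 under miR-4672, and -0.30 in mock. Between 14 (miR-4672) and 28 (miR-6514-5p and miR-3126-5p) of them fell and 1 to 3 rose. Adjusted over the list alone, 22 (miR-4672) to 31 (miR-6514-5p) fell. H2BC14 was 6.52-fold lower under miR-6514-5p (444 against 2891, log2 fold change -2.70 ± 0.18, limma adjusted p = 1.6e-10). H2BC5 went the other way under miR-6859-3p, 2.30-fold higher (log2 fold change 1.20 ± 0.21, limma adjusted p = 6.4e-04), which did not pass with only the 6 arrays of the comparison (adjusted p = 0.087). Histone genes are near-identical copies whose probes can share targets, so values of single members are uncertain. All 7 list calls passed camera, and those of miR-4672 and miR-6859-3p ended with an estimated correlation (adjusted p = 0.076 and 0.061) and against mock (adjusted p = 0.26 and 0.13). Set against mock the histone medians were nearer 0, at -0.71 under miR-6514-5p, -0.43 under miR-3126-5p, -0.33 under miR-134-3p, -0.25 under miR-34b-3p, -0.29 under miR-224-3p, -0.17 under miR-6859-3p and -0.07 under miR-4672. H2BC5, lower in mock than with the control miRNA, was 2.25 higher under miR-6859-3p than in mock on the log2 scale.

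**Figure D3:**
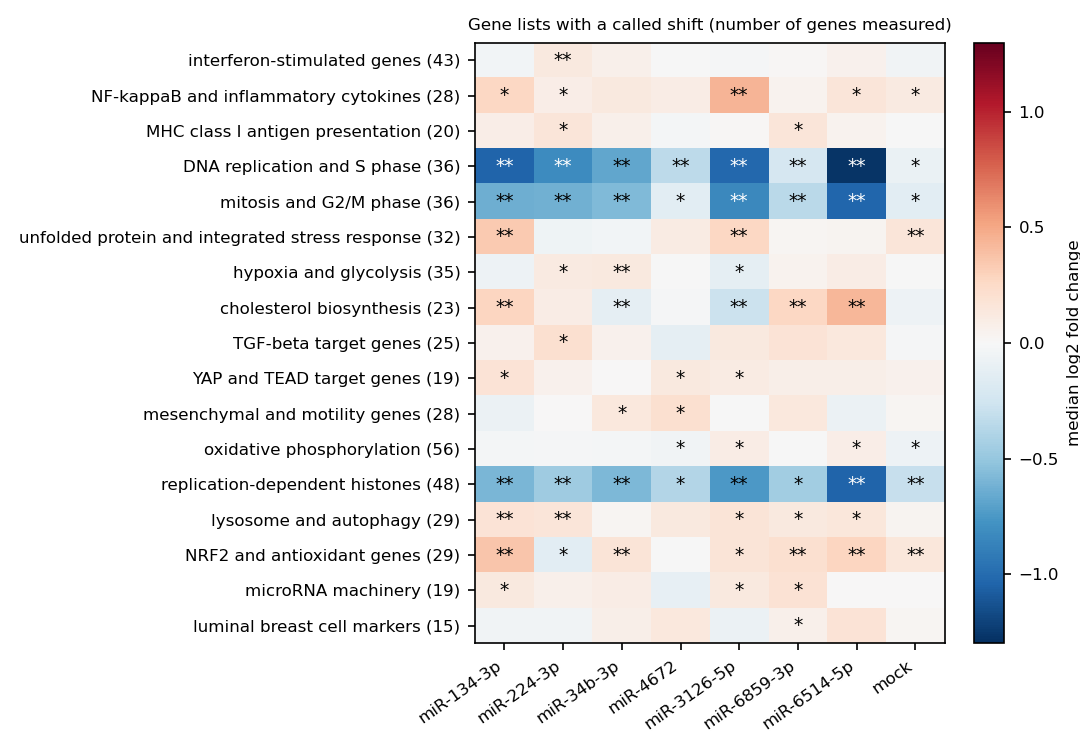
Median log2 fold change against the control miRNA (colour) of each gene list with a called shift (rows, number of measured genes in parentheses) in the 8 comparisons (columns), where 1 star marks a camera call at adjusted p under 0.05 and 2 stars a call that held with an estimated correlation. The DNA replication list runs from -1.27 under miR-6514-5p to -0.09 in mock.

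Under miR-134-3p, 1241 genes rose and 1383 fell. The rise of GDF15, a secreted cytokine of cell stress, was the largest, from an intensity of 640 to 3081 (log2 fold change 2.27 ± 0.09, SE, limma adjusted p = 1.1e-13), and IL24, a cytokine of the IL-10 family, and RHOB, a small GTPase, rose 3.42-fold and 3.17-fold. AOX1, aldehyde oxidase, was 5.40-fold lower, ASF1B, a histone chaperone, 5.13-fold lower and CHCHD10, a mitochondrial protein, 3.50-fold lower. Genes of the unfolded protein and integrated stress response moved up, with 19 of 32 members higher, 1 lower and 12 neither (23 and 2 adjusted over the list alone; camera adjusted p = 1.6e-08). Among them were SLC7A11, the cystine transporter (0.97 in log2), the endoplasmic reticulum chaperone DNAJB9 (0.70), and TRIB3, a target of the stress factor ATF4 (0.64). Of 29 NRF2 and antioxidant genes 15 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 5.5e-09), among them ME1 (0.94), ABCC3 (0.94) and TXNRD1 (0.78), the last of which did not pass against mock (adjusted p = 0.24). Of 23 cholesterol biosynthesis genes 9 rose and none fell (9 and 0 adjusted over the list alone; adjusted p = 1.1e-06), including HMGCS1 (1.12), MSMO1 (0.97) and IDI1 (0.80). Lysosome and autophagy genes rose in 7 of 29 cases (11 and 1 lower adjusted over the list alone; adjusted p = 5.9e-04), among them the autophagy receptors OPTN (0.84) and SQSTM1 (0.83). These 4 calls held with an estimated correlation, whereas 3 others did not. Of 28 NF-kappaB and inflammatory cytokine genes 8 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.14 with an estimated correlation). CXCL8, interleukin 8, rose by 1.03 and ICAM1, an adhesion molecule, fell by 0.96. Of 19 YAP and TEAD targets 6 rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.02, and adjusted p = 0.11 with an estimated correlation). Of 19 genes of the microRNA machinery 5 rose (5 adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.10 with an estimated correlation), AGO2, an Argonaute protein, by 0.44. The NF-kappaB and YAP calls also ended against mock (adjusted p = 0.24 and 0.12), and the YAP call without replicate 3 of miR-134-3p (adjusted p = 0.057). With only the 6 arrays of the comparison the YAP and machinery calls ended (adjusted p = 0.067 and 0.068). Against mock the log2 fold changes were smaller for IL24 (1.15), SLC7A11 (0.49), MSMO1 (0.57) and OPTN (0.54).

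Under miR-224-3p, 1177 genes rose and 1180 fell. IL24 rose 6.89-fold, from 145 to 999 (log2 fold change 2.78 ± 0.18, limma adjusted p = 3.4e-10), RHOB 4.80-fold, and DUSP1, a phosphatase of MAP kinases, 2.85-fold. G0S2, an inhibitor of triglyceride lipase, was 3.91-fold lower, BANF1, a chromatin protein of the nuclear envelope, 3.67-fold, CILK1, a ciliary kinase, 3.33-fold, ARPC5, a subunit of the actin-nucleating Arp2/3 complex, 3.06-fold, and LBR, the lamin B receptor, 2.84-fold lower. The interferon-stimulated genes rose here and passed in no other comparison, with 9 of 43 members higher and none lower (10 and 0 adjusted over the list alone; camera adjusted p = 0.006, and 0.011 with an estimated correlation). Among them IFIT2 rose by 1.16, SAMD9 by 0.57 and OAS2 by 0.51. Lysosome and autophagy genes rose in 12 of 29 cases and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 2.8e-05), with OPTN at 0.83 and the protease CTSB at 0.58. TGF-beta targets were higher in 8 of 25 cases and lower in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0065, and 0.053 with an estimated correlation), TGFBI rising by 1.20 and LTBP1 by 1.08 while FN1, fibronectin, fell by 0.64. NRF2 and antioxidant genes moved down, 7 of 29 lower and 2 higher (7 and 2 adjusted over the list alone; adjusted p = 0.028, and 0.14 with an estimated correlation), PIR falling by 1.12 and SLC7A11 by 0.85. Hypoxia and glycolysis genes were higher in 6 of 35 cases and lower in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0085, then 0.085), with the glucose transporter SLC2A3 at 0.85 and PGAM1 at -0.77. MHC class I antigen presentation was higher in 4 of 20 (5 adjusted over the list alone; adjusted p = 0.0083, then 0.10), with PSMB10 at 0.45. NF-kappaB genes were higher in 6 of 28 (6 adjusted over the list alone; adjusted p = 0.013, then 0.19), with SOD2 at 0.71, and this call ended against mock (adjusted p = 0.50). The NRF2 call also ended without replicate 2 of miR-224-3p (adjusted p = 0.093) and with only the 6 arrays of the comparison (adjusted p = 0.051). Against mock OPTN was at 0.53, SLC2A3 at 1.36 and SLC7A11 at -1.33.

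Under miR-34b-3p the response was the smallest of the 7 by count in the main fit, with 667 genes higher and 616 lower. With only the 6 arrays of a comparison miR-4672 had fewer (682 against 739), and with housekeeping centring miR-6859-3p had fewer. WBP1L rose 3.12-fold, RHOB 2.75-fold, KLF2, a transcription factor of the Kruppel-like family, 2.15-fold and MAPK6, an atypical MAP kinase, 2.09-fold. DENND6A, a regulator of Rab GTPases, was 2.98-fold lower (267 against 796, log2 fold change -1.58 ± 0.07, limma adjusted p = 1.8e-12), ESPL1, the protease separase that opens sister chromatids, 2.55-fold, the zinc transporter SLC39A9 2.43-fold, and CAPZA1, a subunit of the actin capping protein, 2.33-fold lower. Hypoxia and glycolysis genes rose in 9 of 35 cases and none fell (13 and 0 adjusted over the list alone; camera adjusted p = 5.7e-06), among them HK2, hexokinase 2 (0.48), the collagen hydroxylase P4HA1 (0.46), and VEGFA (0.56), which did not pass against mock (adjusted p = 0.11). Of 29 NRF2 and antioxidant genes 6 rose and none fell (8 adjusted over the list alone; adjusted p = 1.2e-04), with ME1 at 0.72, but the list was no longer called against mock (median 0.04, adjusted p = 0.34). The median of the cholesterol list was lower (-0.12, adjusted p = 0.0014), with 2 of 23 members lower, HMGCS1 (-0.44) and FDPS (-0.43), and 2 adjusted over the list alone. This call held with an estimated correlation (adjusted p = 0.045) but ended against mock (adjusted p = 0.064), where neither gene passed (adjusted p = 0.71 and 0.071). The mesenchymal and motility list was higher (7 of 28 higher, 2 lower, and 8 and 2 adjusted over the list alone; adjusted p = 0.0027, and 0.069 with an estimated correlation), with CAV2, a caveolin, at 0.87, and it too ended against mock (adjusted p = 0.10). WBP1L, itself higher in mock than with the control miRNA, was 0.54 higher in log2 than in mock (adjusted p = 0.0017), against 1.64 over the control, and CAV2 was 0.56 higher than in mock.

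Under miR-4672, 996 genes rose and 932 fell. CRISPLD2, a secreted protein, rose 3.35-fold (219 to 734, log2 fold change 1.74 ± 0.10, limma adjusted p = 9.7e-11), ITGB3, integrin beta 3, 2.59-fold, TIMP3, an inhibitor of matrix proteases, 2.48-fold, and THBS1, thrombospondin 1, 2.29-fold. MRPS23, a mitochondrial ribosomal protein, was 3.80-fold lower, TPI1, triose phosphate isomerase of glycolysis, 3.62-fold, DDB1, a subunit of CUL4 ubiquitin ligases, 3.11-fold, and CYCS, cytochrome c, 2.90-fold lower. Mesenchymal and motility genes were higher in 9 of 28 cases and lower in 3 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0075, and 0.10 with an estimated correlation), with SNAI2 at 0.84 and CAV1 at -0.79. This call ended against mock (adjusted p = 0.080) and without replicate 3 of miR-4672 (adjusted p = 0.064). Oxidative phosphorylation genes were lower in 6 of 56 cases and higher in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.0075, then 0.14), COX7B falling by 1.32, and against mock there was no call and the median turned from -0.05 to 0.04 (adjusted p = 0.72). YAP and TEAD targets were higher in 4 of 19 (5 adjusted over the list alone; adjusted p = 0.028, then 0.13), ANKRD1 rising by 0.64, and the call ended against mock (adjusted p = 0.26), with mock and control together (0.086), with only the 6 arrays of the comparison (0.12) and without replicate 2 or 3 of miR-4672 (adjusted p = 0.10 and 0.12). Against mock TIMP3 was 0.81 and SNAI2 0.46 higher in log2. Replicate 1 of miR-4672 stood apart from the other 2 arrays, with a root mean square deviation of 0.233 from its group mean against 0.128 to 0.181 on the other 26 arrays. Without it 1487 genes changed, 784 higher and 703 lower.

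Under miR-3126-5p, 1240 genes rose and 1215 fell. IL24 rose 5.15-fold and IL1B, interleukin 1 beta, 5.12-fold, from 208 to 1063 (log2 fold change 2.36 ± 0.14, limma adjusted p = 8.8e-11), MMP1, a collagenase, 3.13-fold, BCL2A1, an inhibitor of apoptosis, 2.54-fold and STC1, stanniocalcin 1, 2.49-fold. PLK1 was 3.93-fold lower, ASF1B 3.56-fold and UCP2, a mitochondrial carrier, 3.53-fold lower. Of 28 NF-kappaB and inflammatory cytokine genes 15 rose and none fell (17 and 1 adjusted over the list alone; camera adjusted p = 8.2e-08, and 0.011 with an estimated correlation), among them CCL20 (1.24) and PTGS2 (1.18), the latter not past the threshold against mock (adjusted p = 0.11). The stress response list rose (13 of 32 higher, 2 lower, and 17 and 3 adjusted over the list alone; adjusted p = 2.8e-05, and 0.036 with an estimated correlation), with DNAJB9 at 0.66 and PDIA4 at 0.50, while the amino acid transporter SLC7A5 fell by 1.05. Against mock this call stood at the threshold and no longer passed (median 0.14, adjusted p = 0.050). Cholesterol biosynthesis genes fell in 9 of 23 cases and none rose (10 and 0 adjusted over the list alone; adjusted p = 1.2e-04), with MVK, mevalonate kinase, at -0.73 and ACAT2 at -0.53, which held with an estimated correlation (adjusted p = 0.019). Hypoxia and glycolysis genes fell in 11 of 35 cases and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.0029, and 0.053 with an estimated correlation), NDRG1 falling by 0.98 and LOX, lysyl oxidase, by 0.76. Further calls were lost with an estimated correlation, whose adjusted p stands second for each. Lysosome and autophagy genes were higher in 9 of 29 cases and lower in 1 (12 and 3 adjusted over the list alone; adjusted p = 0.013, then 0.11), with NPC1, a lysosomal cholesterol exporter, at 0.79. NRF2 genes were higher in 8 of 29 and lower in 3 (13 and 4 adjusted over the list alone; adjusted p = 0.0083, then 0.085). The microRNA machinery was higher in 4 of 19 (4 and 1 lower adjusted over the list alone; adjusted p = 0.019, then 0.097), with DICER1, the nuclease that makes miRNAs, at 0.50. Oxidative phosphorylation genes were higher in 7 of 56 and lower in 1 (9 and 3 adjusted over the list alone; adjusted p = 0.017, then 0.19). YAP and TEAD targets were higher in 3 of 19, NT5E itself among them, and lower in 1 (3 and 1 adjusted over the list alone; adjusted p = 0.044, then 0.15). The NRF2 and YAP calls ended against mock (adjusted p = 0.71 and 0.34), and under cyclic loess the lysosome, oxidative phosphorylation and YAP calls ended (adjusted p = 0.053, 0.16 and 0.12). Without the dimmest genes the NRF2, oxidative phosphorylation and YAP calls ended (adjusted p = 0.052, 0.057 and 0.092). With only the 6 arrays of the comparison the machinery and YAP calls ended (adjusted p = 0.074 and 0.084). Single arrays also ended calls, control replicate 1 that of oxidative phosphorylation (adjusted p = 0.058), and control replicate 2 and replicates 1 and 3 of miR-3126-5p that of YAP (adjusted p = 0.080, 0.054 and 0.074). Against mock MMP1 was at 0.99 in log2, CCL20 at 0.77, PDIA4 at 0.28, MVK at -0.47 and DICER1 at 0.79.

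Under miR-6859-3p, the miRNA with the highest NT5E, 825 genes rose and 591 fell. TMEM64 rose 2.89-fold (262 to 755, log2 fold change 1.53 ± 0.10, limma adjusted p = 9.8e-10), MYO5B, an unconventional myosin of vesicle transport, 2.61-fold, HMGA2, a chromatin architectural protein, 2.26-fold, and CHRNA1, the acetylcholine receptor subunit, 2.22-fold. PEBP1, the Raf kinase inhibitor protein, was 3.02-fold lower, ALDH9A1, an aldehyde dehydrogenase, 3.00-fold, IL7R, the interleukin 7 receptor, 2.75-fold and SBDS, a factor of ribosome maturation, 2.73-fold lower. Of 29 NRF2 and antioxidant genes 9 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 3.3e-05, and 0.011 with an estimated correlation), with ME1 at 0.72, while TKT, transketolase, fell by 1.03. This call ended against mock (median 0.08, adjusted p = 0.14). Of 23 cholesterol biosynthesis genes 8 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 4.8e-04, and 0.030 with an estimated correlation), MSMO1 rising by 0.85 and PMVK, phosphomevalonate kinase, falling by 1.13. Further calls were lost with an estimated correlation, whose adjusted p again stands second. Lysosome and autophagy genes were higher in 9 of 29 cases and lower in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.0078, then 0.091), with the protease CTSL at 0.43, and against mock this call stood at the threshold and no longer passed (median 0.11, adjusted p = 0.050). MHC class I antigen presentation genes were higher in 3 of 20 (4 adjusted over the list alone; adjusted p = 0.024, then 0.15), with TAPBP, a chaperone of peptide loading, at 0.35. TAPBP did not pass with only the 6 arrays of the comparison (adjusted p = 0.052), and the list call ended under cyclic loess (adjusted p = 0.065) and without the dimmest genes (0.070). The microRNA machinery was higher in 3 of 19 (4 adjusted over the list alone; adjusted p = 0.027, then 0.11), with DICER1 at 0.49. The luminal breast cell markers were higher in 4 of 15 cases (6 and 1 lower adjusted over the list alone; adjusted p = 0.040, then 0.19), with KRT8, a keratin, at 0.33, which did not pass with only the 6 arrays of the comparison (adjusted p = 0.057). The machinery and luminal calls each ended when replicate 2 of the control miRNA (adjusted p = 0.071 and 0.098) or replicate 3 of miR-6859-3p (adjusted p = 0.057 and 0.059) was left out, and the luminal call also without replicate 1 of miR-6859-3p (adjusted p = 0.060) or the dimmest genes (0.057). With only the 6 arrays of the comparison both ended (adjusted p = 0.057 and 0.079). TMEM64, itself higher in mock than with the control miRNA, was 0.68 higher in log2 than in mock, MYO5B 0.66, MSMO1 0.45 and DICER1 0.78.

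Under miR-6514-5p, which changed the most genes in the main fit, 1479 rose and 1343 fell. With only the 6 arrays of a comparison miR-3126-5p changed more (2367 against 2295), and housekeeping centring and array weights also put other miRNAs first. Apart from histones, DTL was 4.66-fold lower (848 to 182, log2 fold change -2.22 ± 0.13, limma adjusted p = 1.7e-11), CDC6, a licensing factor of replication origins, 4.39-fold lower and ASF1B 4.32-fold lower. WBP1L rose 2.69-fold, IL1B 2.59-fold, CACUL1, a regulator of cell cycle kinases, 2.44-fold, and CPA4, a carboxypeptidase, 2.30-fold. Of 23 cholesterol biosynthesis genes 11 rose and 1 fell (13 and 3 adjusted over the list alone; camera adjusted p = 1.1e-04, and 0.019 with an estimated correlation), among them HMGCS1 (1.05) and SQLE, squalene epoxidase (0.84). Of 29 NRF2 and antioxidant genes 13 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 2.0e-05, and 0.010 with an estimated correlation), with the aldo-keto reductase AKR1C3 at 0.91 and ME1 at 0.79. Oxidative phosphorylation genes were higher in 10 of 56 cases and lower in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.0052, and adjusted p = 0.13 with an estimated correlation), SDHC rising by 0.51 and ATP5F1C by 0.43, and this call ended under cyclic loess (adjusted p = 0.056). NF-kappaB genes were higher in 5 of 28 cases (8 adjusted over the list alone; adjusted p = 0.028, and adjusted p = 0.26 with an estimated correlation). Lysosome and autophagy genes were higher in 7 of 29 and lower in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.028, and adjusted p = 0.15 with an estimated correlation). Both calls ended against mock (adjusted p = 0.58 and 0.10) and without the dimmest genes (0.052 and 0.058), and that of lysosome and autophagy also under cyclic loess (0.094), with the mean of probe sets (0.11) and with only the 6 arrays of the comparison (0.059). They also ended when 1 array of miR-6514-5p was left out, replicate 3 for NF-kappaB (adjusted p = 0.25) and replicate 2 for lysosome and autophagy (adjusted p = 0.070). WBP1L was 1.43 above the control in log2 but only 0.33 above mock (adjusted p = 0.032), and CACUL1 1.29 above the control and 0.75 above mock.

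Mock differed from the control miRNA in 133 genes, 108 of them higher and 25 lower, which shows how the second reference lay against the first. WBP1L was 2.15-fold higher in mock (541 against 252 with the control miRNA, log2 fold change 1.10 ± 0.10, limma adjusted p = 4.6e-06), NCBP2, a subunit of the nuclear cap-binding complex, 1.87-fold and TMEM64 1.80-fold higher. H2BC5 was 2.07-fold lower, KLHDC3 1.64-fold, CDC25A, a phosphatase that starts S phase, 1.55-fold, and MICB, a stress ligand of natural killer cells, 1.51-fold lower. The histone list was lower, with 1 of 48 members lower and 12 adjusted over the list alone (median -0.30, camera adjusted p = 2.1e-11, and 0.025 with an estimated correlation). NRF2 genes were higher, 2 of 29 and 4 adjusted over the list alone (adjusted p = 5.4e-05, then 0.013), and so was the stress response list, 0 of 32 and 4 adjusted over the list alone (median 0.16, adjusted p = 5.4e-06, then 0.024). The other 4 calls were lost with an estimated correlation, whose adjusted p stands second for each. The median of the mitosis list was -0.14, with 3 of 36 lower (4 lower and 1 higher adjusted over the list alone; adjusted p = 1.6e-05, then 0.077). That of oxidative phosphorylation was -0.07, with 0 of 56 called and 0 adjusted over the list alone (adjusted p = 1.9e-04, then 0.052). That of NF-kappaB was 0.12, with 0 of 28 called and 2 higher adjusted over the list alone (adjusted p = 0.0024, then 0.11). That of DNA replication was -0.09, with 0 of 36 called and 1 higher adjusted over the list alone (adjusted p = 0.013, then 0.35), and its call ended without control replicate 2 (adjusted p = 0.091) or mock replicate 2 (adjusted p = 0.053). All 10 genes taken by rule for mock lost their call when only the 6 arrays of this comparison were fitted. The call of H2BC5 also ended without control replicate 2 or 3 or mock replicate 1 or 3 (adjusted p from 0.061 to 0.083), with a log2 fold change of -0.69 without control replicate 3, and that of CDC25A without any 1 control replicate or mock replicate 2 (adjusted p from 0.052 to 0.11). Without control replicates 1, 2 and 3 in turn 60, 82 and 75 genes changed, and without mock replicates 1, 2 and 3 101, 81 and 63, with 50 to 81 higher and 10 to 20 lower in these fits.

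A set of genes moved in the same direction under all 7 miRNAs, with 50 higher and 43 lower. Higher were NCBP2 (log2 fold change 0.70 to 1.29 over the 7), GCSH, a protein of the glycine cleavage system (0.69 to 1.17), RNF13, a ubiquitin ligase of endosomes (0.68 to 1.10), HDAC11, a histone deacetylase (0.63 to 1.04), and NTN4, the matrix protein netrin 4 (0.62 to 0.92). Lower were the histone genes H2BC13 (-1.91 to -1.14), H2BC14 (-2.70 to -1.08), H2BC11 (-2.06 to -0.98) and H3C2 (-1.91 to -0.86), and RELN, the matrix protein reelin (-1.28 to -0.88). In 100 simulations of unchanged groups against shared control arrays the highest count was 0 in either direction. Almost no gene passes in such sets, so that 0 was nearly certain in advance. Independent lists would share 6.9e-05 and 4.3e-05 genes, a figure that leaves out the shared controls. Neither value tells how many genes the shared controls alone would give with lists as long as the real ones. The 3 control arrays could not be split with 2 arrays in each part, so part of the 50 and 43 may come from the shared controls. Without replicate 3 of the control miRNA 33 genes were higher and 26 lower under all 7, and with mock as the baseline 16 and 13. Against mock, NCBP2, GCSH, RNF13 and HDAC11 did not pass under most of the miRNAs, and NTN4 (0.21 to 0.51), RELN (-0.92 to -0.51), H2BC11 (-1.57 to -0.49) and H2BC14 (-2.45 to -0.83) passed under all 7 with smaller changes. HDAC11 passed under none of the 7 with only the 6 arrays of a comparison (adjusted p from 0.089 to 0.27) and under miR-34b-3p alone with mock and control together (adjusted p from 0.086 to 0.52 for the other 6). Its call also ended with array weights under miR-134-3p, miR-4672 and miR-3126-5p (adjusted p = 0.094, 0.099 and 0.068), and under 5 miRNAs without control replicate 1 (0.064 to 0.18) or 3 (0.082 to 0.27). It ended as well without 1 array of the miRNA itself under miR-134-3p, miR-224-3p, miR-4672 and miR-3126-5p (adjusted p from 0.050 to 0.20), and that of NCBP2 under miR-6859-3p with mock and control together (0.13). Of the lower genes, H3C2 did not pass against mock under miR-224-3p, miR-34b-3p, miR-4672 and miR-6859-3p (adjusted p = 0.053, 0.33, 0.52 and 0.46), nor H2BC13 under miR-4672, miR-3126-5p and miR-6859-3p (adjusted p = 0.34, 0.081 and 0.065). H3C2 also ended with only the 6 arrays of the comparison under miR-34b-3p and miR-4672 (adjusted p = 0.069 and 0.13). Under miR-4672 the calls of H3C2 and H2BC13 ended without control replicate 3 or replicate 1 of miR-4672 (adjusted p from 0.054 to 0.14), and that of H2BC13 also without control replicate 1, without replicate 2 or 3 of miR-4672, and with mock and control together (0.054 to 0.068). The sign of NCBP2 and HDAC11 turned under several (NCBP2 -0.21 under miR-6859-3p, HDAC11 -0.22 under miR-134-3p), while in mock itself NCBP2 was higher than in the control miRNA group (0.91, limma adjusted p = 1.8e-04).

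The fold changes of the 7 miRNAs correlated across genes, though no more closely than those of unchanged groups that share the controls. Over the 21 pairs the Pearson correlation across genes had a median of 0.46 and ranged from 0.25 to 0.64, where genes are not independent replicates. Unchanged groups simulated against the same controls gave a mean of 0.50, since every comparison shares the control arrays. The mean covariance was 0.0349 against 0.0114 simulated, a difference of 0.0235. The simulation covers only chance values of the control arrays. The difference therefore still holds any real offset of the control miRNA group, beside what the miRNAs share. With the second miRNA of each pair set against mock, so that no array was shared, the median correlation was 0.21 (0.02 to 0.43) and the mean covariance 0.0157.

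Of the 29 lists tested, 12 were called in none of the 8 comparisons. The list of adenosine and ATP metabolism at the cell surface, to which NT5E belongs, had medians from -0.03 to 0.11 over 33 genes (lowest camera adjusted p 0.11), and at most 6 members changed in a comparison. The lists of immune checkpoint and natural killer ligands (medians -0.04 to 0.10), p53 targets (-0.15 to 0.12), apoptosis regulators (-0.03 to 0.11), the cytosolic heat shock response (-0.08 to 0.04), fatty acid synthesis and oxidation (-0.01 to 0.11), epithelial junctions (-0.09 to 0.11) and ribosomal proteins (-0.02 to 0.06) also had no call. Neither did the markers of basal breast cells (-0.29 to 0.07), melanocytes (-0.15 to 0.26), leukocytes (-0.01 to 0.14) and fibroblasts (-0.15 to 0.09). For these 11 lists the lowest camera adjusted p ranged from 0.057 for epithelial junctions to 0.39 for fatty acid genes.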

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

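The alternatives were fixed before the data were examined except 2 chosen after seeing the data, the comparison of each miRNA with the mean of the other 6 and the requirement of the same direction in mock. The 3 arrays per group limit what can be seen. In simulation most changes of 0.25 in log2 went uncalled, though with far fewer changed genes than were called under the real miRNAs. The NT5E values of the 7 miRNAs stayed above the baseline in every alternative. NT5E passed over all genes in more comparisons under housekeeping centring (miR-134-3p 0.22, adjusted p = 0.017, and miR-224-3p 0.23, 0.018), with trend and robust variances (0.14, 0.15, 0.13 and 0.17 for miR-134-3p, miR-224-3p, miR-34b-3p and miR-4672, adjusted p = 0.017, 0.012, 0.043 and 0.0065) and without the dimmest genes (miR-4672, 0.17, adjusted p = 0.040, fewer genes tested), and did not pass for miR-6514-5p with only the 2 groups (0.24, adjusted p = 0.086, fewer arrays). Against mock it was called for the same 3 miRNAs (adjusted p = 0.021, 0.0024 and 0.047). Fits of only 2 groups, with fewer arrays, called 739 genes for miR-34b-3p, 682 for miR-4672, 885 for miR-6859-3p and 0 for mock, and 18 higher and 15 lower under all 7 miRNAs. With mock as the baseline miR-34b-3p had 828 genes, and 16 were higher and 13 lower under all 7. With mock and control together 26 were higher under all 7. Array weights gave 350 genes for mock (271 higher, 79 lower). At adjusted p under 0.01 the counts were 1641 (miR-134-3p), 1440 (miR-224-3p), 731 (miR-34b-3p), 1099 (miR-4672), 1548 (miR-3126-5p), 784 (miR-6859-3p), 1782 (miR-6514-5p) and 60 (mock), and with at least 2-fold change 175, 107, 38, 108, 171, 55, 263 and 2 in that order. An estimated correlation left 37 list calls and fry, which does not set a list against other genes, gave 112. The median correlation with the second miRNA against mock was 0.21. The alternatives chosen after seeing the data gave 18 genes higher and 2 lower in all 8 comparisons, and 3734 (miR-4672) and 2397 (miR-6859-3p) genes against the mean of the other 6. Leaving out 1 array gave 60 to 101 genes for mock (60 without control replicate 1, 82 and 75 without control replicates 2 and 3, 81 and 63 without mock replicates 2 and 3). It gave 33 to 50 higher and 26 to 45 lower genes under all 7 (33 and 26 without control replicate 3). Without control replicate 1 the genes higher were 442 for miR-34b-3p (from 667) and 542 for miR-6859-3p (from 825). The other total counts kept within 1.5 times. With mock as the baseline, values turned for NCBP2 (miR-134-3p -0.08, miR-224-3p -0.08, miR-4672 -0.10, miR-6859-3p -0.21), HDAC11 (miR-134-3p -0.22, miR-224-3p -0.06, miR-4672 -0.11, miR-3126-5p -0.21), and under miR-4672 ANLN (-0.02) and RBMS3 (-0.07), none called (adjusted p from 0.35 to 0.92), as did list medians under miR-4672 (mitosis -0.14 to 0.02, oxidative phosphorylation -0.05 to 0.04) and, to -0.00, NF-kappaB under miR-224-3p and miR-6514-5p. The cause of these changes was not tested except where fewer genes or arrays are named. Of 416 values of single genes and 69 list calls, only the 2 groups ended 57 and 9, cyclic loess 5 and 6, housekeeping centring 5 and 0, and trend and robust variances 0 and 0. Mock as the baseline ended 79 of 401 and 19 of 62 (and turned the 10 above), and leaving out the dimmest genes 0 of 403 and 8 of 69. Scalings moved the median of all genes by at most 0.08. The other deposited table holds the same values and was not run, and the seed-match result and its 5 alternatives were not run for want of an annotation. With the replicate number as a replicate block, 2538, 2321, 1222, 1836, 2428, 1376, 2745 and 117 genes changed (7 miRNAs in the order above, then mock), 3 gene calls and no list call ended, and deviations of same-numbered arrays correlated at -0.01 on average (-0.24 to 0.14, 8 of 108 pairs above 0.1), so samples share only a number.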

Other observations

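The comparison of each miRNA with the mean of the other 6 and, for replicate 1 of miR-4672, the tests of a mixture and of a stronger response, with the minimum correlation set for a mixture, were chosen only after the results were seen. Setting each miRNA against the mean of the other 6 takes the control arrays out and brings out what set each miRNA apart. Its list tests were run only at the preset correlation of 0.01, where a call alone is weak evidence. For miR-6859-3p the DNA replication list was higher than under the others (median 0.65, camera adjusted p = 4.4e-31), with GINS2 at 1.15 and DTL at 1.39, and SBDS (-2.03), PEBP1 (-1.83) and ALDH9A1 (-1.70) were the lowest. For miR-4672 the mitosis list was higher (0.63, adjusted p = 5.6e-16), as were CRISPLD2 (1.47), ITGB3 (1.46) and BMP4, a secreted growth factor (1.21), while MRPS23 (-2.05), TPI1 (-1.82) and VTA1, a factor of endosome sorting (-1.66), were lower. For miR-6514-5p both the DNA replication (-0.54, adjusted p = 1.7e-24) and mitosis lists (-0.46, adjusted p = 9.0e-19) were lower, with CHCHD3, a mitochondrial inner membrane protein, at -1.84, ARCN1, a coatomer subunit, at -1.77 and the protease ADAM10 at -1.61.

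In the same comparison the cholesterol list was relatively higher for miR-6514-5p (0.36, camera adjusted p = 7.8e-06), miR-134-3p (0.25, adjusted p = 2.1e-09) and miR-6859-3p (0.20, adjusted p = 0.0038). It was relatively lower for miR-3126-5p (-0.39, adjusted p = 3.2e-12) and miR-34b-3p (-0.28, adjusted p = 2.5e-10). The stress response list was higher for miR-134-3p (0.25, adjusted p = 1.4e-11) and miR-3126-5p (0.17, adjusted p = 1.5e-06) and lower for miR-224-3p (-0.19, adjusted p = 1.2e-06) and miR-34b-3p (-0.16, adjusted p = 2.8e-05). GDF15 was 1.95 higher under miR-134-3p than the mean of the others, and IL24 was 2.01 higher under miR-224-3p, 1.52 higher under miR-3126-5p, and lower under miR-4672 (-1.65) and miR-6859-3p (-1.66). IL1B (1.64) and MMP1 (1.72) were higher under miR-3126-5p. The genes named for this comparison were chosen after their values were seen. Against the control miRNA instead, the lower cholesterol list of miR-34b-3p had 2 of 23 members called, and its call ended against mock (camera adjusted p = 0.064). The stress response list was not called against the control miRNA for miR-224-3p (median -0.06, camera adjusted p = 0.11) or miR-34b-3p (-0.04, adjusted p = 0.27). Its lower values for these miRNAs are thus relative to a mean that includes miRNAs with a raised list.

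Some genes were higher in mock and under all 7 miRNAs than in the control miRNA group, 18 against 2 lower, among them NCBP2, MFSD1, a lysosomal membrane protein, and SDC4, the proteoglycan syndecan 4, named after their values were seen. Chance values of the 3 control arrays could not be judged from the 100 simulated sets, whose highest count was 0. Those sets held no changed gene, so almost no gene passed in them and a shared gene could hardly arise. The scaling of the control arrays is argued against only as far as 2 rescalings could change it. Under cyclic loess 15 of the 18 were higher in all 8 comparisons (15 genes in all). Under housekeeping centring 16 were (21 in all). These rescalings moved the median of the mock comparison by only -0.01 and -0.00, so most of the 18 were likely to stay. The ratio of 9 genes higher per gene lower only restates the pattern and decides nothing. Chance values of the control arrays, a lowering of these transcripts by the control miRNA and handling that differed for the control samples all stay open.

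The histone and DNA replication lists were lower under the miRNAs than under the control miRNA. A high level in the control arrays alone is argued against, since 12 of the 14 list calls (5 of 7 for histones, 7 of 7 for DNA replication) passed with mock as the baseline too. These calls were made at the preset correlation only and share the same mock arrays, so they are not separate pieces of evidence. The DNA replication medians then ran from -1.16 under miR-6514-5p to -0.15 under miR-6859-3p. The histone medians then were only -0.71 to -0.07 (from -1.04 to -0.38), so part of the histone shift depends on the control arrays as the baseline (mock itself was at -0.30). Loss of transcripts without a poly(A) tail is argued against as the whole cause of both shifts. The DNA replication list, whose transcripts are polyadenylated, was lower under all 7 miRNAs with a lower histone list. For the histone shift alone this loss stays open, since the 2 lists could fall for separate reasons. A smaller share of cells in S phase may underlie both, as a hypothesis: over the 7 miRNAs the medians of the 2 lists correlated (Pearson 0.82, exact permutation p = 0.018, adjusted p = 0.037 over 2 relations; Spearman 0.89, exact permutation p = 0.012; Pearson 0.67 without the 2 miRNAs farthest from the median). The mitosis and G2/M list fell in a similar order, most under miR-6514-5p (-1.03) and least under miR-6859-3p (-0.35) and miR-4672 (-0.14). The correlation therefore does not single out S phase from a wider fall of cell cycle genes. A lower transcription of these genes in unchanged cell cycle phases would give the same correlation, and no measurement of the cycle was analysed here.

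The first replicate of miR-4672 lay apart from the other 2 arrays of its group. Its background was raised, with an antigenomic median of 68.5 against 58.8 to 63.9 on the other 26 arrays, which is consistent with a technical origin. A stronger response to the same miRNA is argued against, since its deviation correlated at 0.01 with the effect of miR-4672 in the other 2 arrays. The highest correlation with the effect of another miRNA was 0.02. By the rule first written for a mixture with RNA of another group, any value above 0.01 would have counted in its favour, but a minimum of 0.1 was added after both values were seen, so a mixture stays open.

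Other groupings of the arrays were counted to see whether chance can be excluded. None of 99 random regroupings of the 27 arrays reached the 6785 genes differing among the groups (highest 348). The real grouping was thus the only 1 of 100 as large, which argues against chance for that count. The 93 genes moved alike by all 7 miRNAs were not reached either (highest 0). Regroupings call few genes, however, so a count of 0 was nearly certain there and decides nothing. The 69 list calls were not reached, but a random regrouping gave up to 58. The real number was the largest, yet chance is not excluded for a single list call. For a single comparison the 10 splits of 6 arrays are too few for a share under 0.05. In fits of 2 groups the real split gave 2015 genes for miR-134-3p, 2060 for miR-224-3p, 739 for miR-34b-3p, 682 for miR-4672, 2367 for miR-3126-5p, 885 for miR-6859-3p and 2295 for miR-6514-5p, where 1 split, the real one, was as large in each and the other splits gave at most 1 gene. For mock the real split gave 0 genes, which all 10 splits reached, and the highest of the others was 1.

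No relation of NT5E to the cell cycle genes was detected. Over the 7 miRNAs its log2 fold change correlated with the median of the DNA replication list at 0.24 (Pearson, exact permutation p = 0.61, adjusted p = 0.61; Spearman 0.18, exact permutation p = 0.71), and at -0.64 without the 2 miRNAs farthest from the median. With 7 values a moderate relation would not be detected.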
